A study of Mus musculus with 15 samples.

How the data were processed

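The study sequenced RNA from 15 libraries of GL261 mouse glioma cells in 5 groups of 3: non-SP, PBS, D-gel@GSNP, L-gel@GSNP and D-gel@NP. Per the labels, the Hoechst-CD133+ cells of the 3 hydrogel groups were put into lyophilised hydrogels for 20 min on ice and then kept with cytokines until Day 6. The PBS group had PBS and cytokines, with no ice step named, and the non-SP cells were untreated; all groups had new medium on days 2 and 4. Comparisons of a hydrogel group with PBS therefore include the ice step. RNA was extracted with TRIzol and sequenced in read pairs. The batch label is the same in all libraries, so no batch could be compared.

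The deposited count table holds whole-number read counts per gene, which the authors made with fastp 0.22.0, HISAT2 2.1.0 and featureCounts on the mouse genome GRCm39; DESeq2 is also named in their notes, and the annotation release and the strand and multi-mapping settings are not stated. The deposited FPKM values were also made by the authors, and for all 34259 genes they equal the count divided by a fixed gene length and by the library's total count, within a relative tolerance of 0.0001. Among genes with 1 to 20 counts, 62.32% to 66.44% of the counts per library were even, where single counts would give about as many odd as even. The cause was not tested; if mates of a pair were counted separately, intervals from counts, which treat counts as independent, are too narrow. Gene symbols and biotypes came from a GENCODE annotation of an earlier genome build, matched by gene identifier (32434 of 34259 matched, 1825 not), so no coordinates are given.

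Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by group (17497 genes), libraries were scaled with TMM factors, and a quasi-likelihood model with a mean for each group was fitted to all 15 libraries together (glmQLFit, glmQLFTest). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison, and changes of at least 2-fold were also counted. The biological coefficient of variation was 8.06%. Intervals of a log2 difference are 95% intervals from the model's standard error. Each of 35 preset gene lists was tested in each comparison with camera of limma 3.58.1, with a preset correlation between genes of 0.01 and again with an estimated correlation, and adjusted over the lists of the comparison. A list needed 3 tested members. Of the 655 genes in these and 6 lists of cell type markers, 631 were in the count table. Distances between libraries are Euclidean distances of log2 CPM of the tested genes.

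Before the data were examined, 9 comparisons, the lists, the tests, the alternatives and a rule for naming genes were fixed. The rule named a panel of 10 genes (Prom1, Abcg2, Abcb1a, Sox2, Nes, Cd44, Olig2, Gfap, Tubb3 and Myc) in every comparison. In the first 6 comparisons it also named the 6 largest rises and the 6 largest falls among called genes with at least 5 CPM in the higher group and groups that did not overlap, and up to 4 members with the lowest adjusted p in each list that passed camera or had 25% of its members called. Symbols of the form Gm with digits or ending in Rik were left out. The text gives a part of the genes so named, and 1 of them is not reported here. The comparison of L-gel@GSNP with D-gel@NP was added after the data were seen.

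The alternatives fixed beforehand were RLE and upper-quartile factors, no filter and a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, a fit of only the 6 libraries compared, a replicate block, leaving out each library of the groups compared in turn, and limma on log2(FPKM + 1) with and without a filter and on log2(FPKM + 0.1). Thinning all libraries to the total of the shallowest, leaving out mitochondrially encoded genes, and leaving out D-gel@NP 1 from every fit were added after the data were seen. Overlaps between comparisons were set against independent calls, and the covariance of the log2 differences against 20 simulations without group differences that kept the shared control.

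The pipeline was tested on simulated data with the same group sizes and depths, in which 100 genes were changed by 1.5-fold and 100 by 2-fold. For D-gel@GSNP minus non-SP it recovered 57% and 69% of them and called 4 unchanged genes of 16216, and over the 10 comparisons simulated camera called 10 of 10 raised lists and 0 unchanged lists. Simulated counts had the dispersions estimated from the data, and each gene was drawn independently. The camera result therefore does not cover lists whose members vary together. Total counts ran from 16.6 M to 98.1 M (mega) per library. Intervals and floors from counts cover counting error only. A group without counts was given a floor of 3 counts over the group. All samples were used. Sequence reads were not analysed here.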

Results

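Gene expression was measured by RNA sequencing in 15 libraries of GL261, a mouse glioma cell line, all labelled Day 6 and all carrying the same batch label. The libraries form 5 groups of 3. The non-SP group held untreated cells outside the side population, the fraction of a culture that pumps out the dye Hoechst. The other groups held cells labelled Hoechst-CD133+ (CD133 is the product of Prom1) that received a cytokine cocktail. Of these, the PBS group had buffer only, and the cells of the D-gel@GSNP, L-gel@GSNP and D-gel@NP groups were taken up in hydrogels. The labels call the hydrogels chiral and tell them apart by the prefixes D and L; GSNP and NP are code names of the load, and the labels do not say what they stand for. The total count per library ran from 16.6 M (D-gel@NP 1) to 98.1 M (L-gel@GSNP 3), a 5.9-fold range (M, mega). The totals were 41.8, 39.3 and 41.6 M for non-SP, 38.5, 42.7 and 39.2 M for PBS and 44.8, 55 and 44.5 M for D-gel@GSNP. They were 35, 43.7 and 98.1 M for L-gel@GSNP and 16.6, 38.7 and 40 M for D-gel@NP. Levels are given below as CPM, counts scaled to a common library total with TMM factors, as mean ± SD with n = 3.

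The D-gel@GSNP libraries lay close to the non-SP libraries, while the other 3 groups lay apart. On the first principal component, which held 50.4% of the variance, the D-gel@GSNP libraries lay between -67.87 and -61.76 and the non-SP libraries between -63.95 and -62.87. The PBS libraries lay between 18.4 and 21.82, the D-gel@NP libraries between 48.72 and 50.83, and the L-gel@GSNP libraries between 57.16 and 58.9. The distance between a non-SP and a D-gel@GSNP library was 67.6 to 73.9, against 67.5 to 69.4 within non-SP and 65.1 to 69 within D-gel@GSNP. Between PBS and D-gel@GSNP it was 113.3 to 123.7. The share of counts on mitochondrially encoded genes was lowest in the same 2 groups, at 2.86% ± 0.055 in non-SP, 3.00% ± 0.316 in D-gel@GSNP, 4.50% ± 0.192 in L-gel@GSNP, 4.63% ± 0.191 in D-gel@NP and 5.97% ± 0.343 in PBS (SD, n = 3).

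The comparison of PBS with non-SP asks how the cytokine-treated cells labelled Hoechst-CD133+ differed from the untreated cells outside the side population; cell population and cytokines changed together. The PBS cells had higher levels of targets of the tumour suppressor p53, of lysosomal, cholesterol synthesis, interferon and inflammatory genes, and lower levels of genes of DNA replication and mitosis. Of these lists only those of p53 targets, lysosomal and interferon genes passed with an estimated correlation. Cdkn1a, which encodes the cell cycle inhibitor p21, was at 341 ± 4.68 CPM against 132 ± 1.01 CPM, 2.58-fold higher. Plk1, a kinase that drives mitosis, was at 49.9 ± 4.48 against 142 ± 1.29 CPM, 2.83-fold lower. By edgeR's quasi-likelihood test 4824 genes were higher and 4564 lower of 17497 tested, and 1632 and 557 of them changed at least 2-fold. The 3 libraries of each group did not overlap for 61.2% of genes, where chance gives 10%.

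Of 22 tested p53 targets 21 rose and none fell, 21 and 0 when adjusted over the list alone, with a mean log2 difference of 1.04 (camera adjusted p = 7.21e-14, and 0.0163 with an estimated correlation). Trp53inp1, which promotes p53-dependent cell death, rose from 70.8 ± 3.98 to 413 ± 24.2 CPM and Ccng1 from 287 ± 3.64 to 790 ± 39.4 CPM. Of 24 DNA replication genes 19 fell and none rose, 20 and 0 when adjusted over the list alone (camera adjusted p = 1.77e-09; adjusted p = 0.182 with an estimated correlation). The replicative helicase genes Mcm2 and Mcm3 were 1.89-fold and 1.74-fold lower. Of 20 G2 and mitosis genes 19 fell and none rose; adjusted over the list alone, 19 fell and 1 rose (camera adjusted p = 1.79e-11; adjusted p = 0.12 with an estimated correlation). Aurka, a kinase of the mitotic spindle, fell from 163 ± 1.58 to 82.8 ± 4.79 CPM. Of 23 DNA repair genes 13 fell and 2 rose, 14 and 2 when adjusted over the list alone (camera adjusted p = 0.0013; adjusted p = 0.224 with an estimated correlation).

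Of 22 lysosome and autophagy genes 19 rose and 1 fell, the same counts as when adjusted over the list alone (camera adjusted p = 2.46e-10, and 0.0163 with an estimated correlation). Ctsd, which encodes the protease cathepsin D, rose 4.13-fold to 427 ± 35.2 CPM. Of 26 interferon response genes 20 rose and 1 fell, as also when adjusted over the list alone (camera adjusted p = 4.04e-06, and 0.0163 with an estimated correlation). The antiviral GTPase gene Mx1 rose from 0.540 ± 0.0244 to 11.1 ± 0.761 CPM and Gbp3, a guanylate-binding protein gene, from 427 ± 3.8 to 996 ± 39.2 CPM. Of 13 genes of MHC class I presentation 9 rose and none fell, again 9 and 0 when adjusted over the list alone (camera adjusted p = 0.00223, and 0.0457 with an estimated correlation). Tapbp and B2m, which encode a loading factor and the light chain of the class I complex, rose 2.94-fold and 1.93-fold. Beside these lists, the summed level of macrophage and microglia markers was 74.5 ± 3.91 CPM in PBS against 11.8 ± 0.0488 CPM in non-SP (SD, n = 3), with Cd68, a lysosomal protein gene, the highest of them at 42.7 and 6.48 CPM. Markers other than Cd68 rose too, such as Csf1r (24.8 against 2.45 CPM) and Itgam (1.8 against 0.0976 CPM). Fcer1g (0.166 against 0.301 CPM) and Tmem119 (0.05 against 0.13 CPM) were lower in PBS, and Tyrobp had no counts in either group.

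Of 23 cholesterol synthesis genes 19 rose and 1 fell, as also when adjusted over the list alone (camera adjusted p = 2.87e-10; adjusted p = 0.151 with an estimated correlation). Msmo1, a sterol demethylating oxidase gene, rose from 51.1 ± 1.37 to 170 ± 9.79 CPM. Of 22 NF-kB and inflammatory genes 13 rose and 2 fell, 14 and 2 when adjusted over the list alone (camera adjusted p = 0.00154; adjusted p = 0.151 with an estimated correlation). The neutrophil-attracting chemokine genes Cxcl5 and Cxcl1 rose 6.80-fold and 5.26-fold. Of 12 ABC transporter genes of drug efflux 9 rose and 1 fell, as also when adjusted over the list alone (camera adjusted p = 0.00167, and 0.0387 with an estimated correlation), and Abcc2 rose from 175 ± 3.65 to 338 ± 10.4 CPM. Of 9 astrocyte genes 6 rose and 1 fell, 7 and 1 when adjusted over the list alone (camera adjusted p = 0.000354, and 0.0457 with an estimated correlation). Those that rose included the lipid carrier gene Apoe, 5.13-fold, and the glutamate transporter gene Slc1a2, 14.5-fold. Of 17 endoplasmic reticulum chaperone genes 13 rose and 1 fell, 14 and 1 when adjusted over the list alone (camera adjusted p = 2.26e-05, and 0.0457 with an estimated correlation), among them Dnajb9, up 3.87-fold.

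Of 14 actin and SRF target genes 9 fell and 1 rose, the same counts as when adjusted over the list alone (camera adjusted p = 0.00284; adjusted p = 0.224 with an estimated correlation). Of 12 Wnt target genes 10 fell and 2 rose, as also when adjusted over the list alone (camera adjusted p = 0.00699; adjusted p = 0.393 with an estimated correlation), among them the feedback inhibitor gene Nkd1, 2.40-fold lower. The largest rises included the tubulin-binding protein genes Tppp and Tppp3, which rose 46.9-fold and 24.4-fold, the water channel gene Aqp1, 26.3-fold, and the transcription factor gene Fos, 22.2-fold. Tppp3 reached 295 ± 20.2 CPM. Among the largest falls were the amino acid transporter gene Slc7a5, from 116 ± 6 to 25.7 ± 4.89 CPM, the glypican gene Gpc3, 4.62-fold, and Col1a1, from 13.4 ± 1.31 to 1.58 ± 1.45 CPM. The log2 difference of Col1a1 was -3.08 and became -4.14 without PBS 3.

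Of the stem cell and differentiation markers chosen in advance, Cd44, which encodes an adhesion receptor, was 2.21-fold higher in PBS at 1160 ± 48 CPM (edgeR adjusted p = 4.36e-15). The dye and drug efflux pump gene Abcb1a was 2.28-fold higher at 41.2 ± 1.88 CPM (edgeR adjusted p = 2.69e-11). Abcg2, the pump that defines the side population, was 1.13-fold higher (edgeR adjusted p = 0.00995); without a filter on low counts its adjusted p was 0.0813. The intermediate filament gene Nes was 2.99-fold lower at 1.24 ± 0.53 CPM (edgeR adjusted p = 4.04e-06), and Myc 1.19-fold lower (edgeR adjusted p = 0.00185). Gfap was at 0.28 ± 0.0214 CPM against 0.105 ± 0.0687 CPM, which did not pass (edgeR adjusted p = 0.101). Prom1 had 2 counts over the 3 non-SP libraries and 19 over PBS, 8 over D-gel@GSNP, 35 over L-gel@GSNP (31 of them in L-gel@GSNP 3) and 10 over D-gel@NP. Olig2 had 4 counts in PBS 2 and none elsewhere, and Tubb3 at most 8 in any group; these 3 genes were too low to test. Prom1 was at 0.141 to 0.179 CPM in the PBS libraries, which is too little to bear out the CD133 label or to speak against it. Sox2 is not analysed here, as the count table has no entry under that symbol. The table holds no gene without counts in every library, so whether Sox2 had no counts or was left out otherwise cannot be told. The list of stem-like markers passed camera in none of the 9 planned comparisons.

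A further 3 lists passed camera, and none of these passed with an estimated correlation. Of 5 Hedgehog pathway genes 4 fell and 1 rose (camera adjusted p = 0.0246, and 0.393 with an estimated correlation), of 15 immediate early genes 8 rose and 3 fell (0.0311 and 0.404), and of 5 metal response genes 4 rose and none fell (0.0301 and 0.12), with the same counts when adjusted over the list alone. Their calls also ended with a filter at 1 CPM in 3 libraries (camera adjusted p = 0.0506 for each); over all alternatives their adjusted p ran from 0.00901 to 0.393, from 0.0137 to 0.404 and from 0.00338 to 0.12. On the log2(FPKM + 1) scale 511 genes in place of 2189 passed the 2-fold limit, and upper-quartile factors gave 5343 genes higher and 4016 lower.

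The comparison of D-gel@GSNP with PBS asks what the loaded D hydrogel did to cells of the same label in the same cytokines. In the D-gel@GSNP libraries a wrong label or shared material cannot be told apart from a treatment effect, as weighed under the other observations. This limit holds for every comparison with D-gel@GSNP. The result was close to a mirror image of the first comparison: replication and mitosis genes rose, and p53 targets, lysosomal, interferon, class I and cholesterol synthesis genes fell, to about the level of the non-SP cells. Of these lists only those of p53 targets, lysosomal and interferon genes passed with an estimated correlation. Plk1 rose from 49.9 ± 4.48 to 155 ± 10.5 CPM, 3.10-fold, beside 142 ± 1.29 CPM in non-SP. Cdkn1a fell from 341 ± 4.68 to 136 ± 4.67 CPM, 2.51-fold, beside 132 ± 1.01 CPM in non-SP. In edgeR's quasi-likelihood test 4802 genes were higher and 4819 lower, 584 and 1638 of them by at least 2-fold. Groups did not overlap for 61% of genes, where chance gives 10%. Of the 9388 genes that differed between PBS and non-SP, 8344 (88.9%) changed in the opposite direction here and 2 in the same direction (Etohd2 and an unnamed gene, ENSMUSG00000120539, named after their values were seen); if the calls were independent, 2581 would be shared. Both comparisons use the PBS libraries, which adds to this number by itself; the covariance of the log2 differences was -0.789, against -0.057 in simulations without group differences that shared these libraries.

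Of 24 DNA replication genes 21 rose and none fell, as also when adjusted over the list alone (camera adjusted p = 1.1e-09; adjusted p = 0.171 with an estimated correlation). Mcm2 rose from 205 ± 2.91 to 409 ± 11.6 CPM and Mcm3 1.88-fold. Of 20 G2 and mitosis genes 19 rose and 1 fell, and the same when adjusted over the list alone (camera adjusted p = 2.62e-10; adjusted p = 0.14 with an estimated correlation), with Aurka 2.14-fold higher. Of 23 DNA repair genes 14 rose and 4 fell, as also when adjusted over the list alone (camera adjusted p = 0.0033; adjusted p = 0.275 with an estimated correlation). Of 22 p53 targets 21 fell and none rose, 21 and 0 when adjusted over the list alone (camera adjusted p = 7.48e-13, and 0.028 with an estimated correlation), and Trp53inp1 fell 6.60-fold.

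Of 22 lysosome and autophagy genes 17 fell and 1 rose, 18 and 1 when adjusted over the list alone (camera adjusted p = 4.58e-09, and 0.028 with an estimated correlation). Ctsd fell from 427 ± 35.2 to 106 ± 2.49 CPM and Gpnmb, a lysosomal membrane glycoprotein gene, from 807 ± 35 to 236 ± 15.5 CPM. Of 26 interferon response genes 20 fell and 1 rose, as also when adjusted over the list alone (camera adjusted p = 9.88e-06, and 0.028 with an estimated correlation), with Mx1 21.8-fold and Gbp3 2.43-fold lower. Of 13 class I presentation genes 8 fell and none rose, again 8 and 0 when adjusted over the list alone (camera adjusted p = 0.00424; adjusted p = 0.0744 with an estimated correlation). Tapbp fell 2.97-fold and B2m 1.88-fold. Beside these lists, the macrophage and microglia markers summed to 12.8 ± 0.404 CPM in D-gel@GSNP against 74.5 ± 3.91 CPM in PBS, and the mitochondrial share was 3.00% against 5.97%.

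Of 23 cholesterol synthesis genes 19 fell and 1 rose, 19 and 2 when adjusted over the list alone (camera adjusted p = 1.1e-09; adjusted p = 0.17 with an estimated correlation), with Msmo1 3.51-fold and Fdps, a farnesyl diphosphate synthase gene, 2.76-fold lower. Of 22 NF-kB and inflammatory genes 11 fell and 3 rose, as also when adjusted over the list alone (camera adjusted p = 0.0041; adjusted p = 0.179 with an estimated correlation), with Cxcl5 7.06-fold lower. Of 12 ABC transporter genes 8 fell and 1 rose, 9 and 2 when adjusted over the list alone (camera adjusted p = 0.0074; adjusted p = 0.0744 with an estimated correlation). Of 9 astrocyte genes 6 fell and 1 rose, 7 and 1 when adjusted over the list alone (camera adjusted p = 0.000908; adjusted p = 0.0744 with an estimated correlation), with Apoe 5.14-fold lower. Of 17 endoplasmic reticulum chaperone genes 12 fell and 2 rose, as also when adjusted over the list alone (camera adjusted p = 0.000203; adjusted p = 0.0809 with an estimated correlation). Actin and SRF target genes rose in 10 of 14 cases and fell in 1, 11 and 1 when adjusted over the list alone (camera adjusted p = 0.000594; adjusted p = 0.17 with an estimated correlation). Of 12 Wnt target genes 10 rose and 2 fell, as also when adjusted over the list alone (camera adjusted p = 0.0041; adjusted p = 0.416 with an estimated correlation), and Nkd1 rose 2.73-fold.

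Among the largest changes, Tppp fell from 48.9 ± 2.58 to 0.771 ± 0.115 CPM, Tppp3 from 295 ± 20.2 to 12.4 ± 0.82 CPM and Aqp1 27.0-fold. Slc7a5 rose 4.89-fold to 126 ± 5.27 CPM and Gpc3 5.16-fold. The serpin gene Serpinb12 had 2 counts over the D-gel@GSNP libraries and 650 over PBS, a depth-scaled ratio of 375 (95% interval 103 to 3110, counting error only). Both counts were in D-gel@GSNP 1, and the log2 difference of -8.29 became -10.88 without that library and -7.69 without D-gel@GSNP 2. Cd44 was 2.14-fold lower at 539 ± 6.97 CPM (edgeR adjusted p = 8.4e-15) and Abcb1a 2.26-fold lower (edgeR adjusted p = 2.59e-11). Nes was 2.73-fold higher (edgeR adjusted p = 1.14e-05) and Myc 1.17-fold higher (edgeR adjusted p = 0.00419; limma on unfiltered log2(FPKM + 1) gave 0.124). Abcg2 did not pass (50 ± 1.78 against 54.3 ± 1.76 CPM, edgeR adjusted p = 0.071), but did with DESeq2 (adjusted p = 0.0395), with upper-quartile factors (0.0044) and with a filter at 1 CPM (0.034). Gfap did not pass either (edgeR adjusted p = 0.413).

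The other 4 lists that passed camera were those of the Hedgehog pathway (adjusted p = 0.0282, and 0.416 with an estimated correlation), the immediate early genes (0.0282 and 0.416), the metal response (0.031 and 0.14) and the YAP targets (0.0387 and 0.502), so none of these 4 passed with an estimated correlation. With a filter at 1 CPM in 3 libraries the camera adjusted p was 0.0562 for the Hedgehog list, 0.0514 for the metal response and 0.0753 for the YAP targets, and the YAP call also ended without PBS 1 (0.0544). Over all alternatives these 3 ran from 0.0111 to 0.416, from 0.0112 to 0.14 and from 0.00585 to 0.502. Upper-quartile factors shifted the median of all genes to -0.102 on the log2 scale and gave 4066 genes higher and 5561 lower, and 530 genes in place of 2222 passed the 2-fold limit on the log2(FPKM + 1) scale.

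The comparison of L-gel@GSNP with PBS asks the same of the L hydrogel with the same load. Genes of the integrated stress response, which cells switch on when amino acids or protein folding fail, were higher, as were genes induced by low oxygen, glycolysis genes and matrix genes. Cholesterol synthesis, respiratory chain, lysosomal, replication and mitosis genes were lower. Among these lists only the integrated stress response passed with an estimated correlation. Asns, which makes asparagine, rose from 78.5 ± 3.4 to 211 ± 12.3 CPM, 2.68-fold, and Vegfa, which encodes a growth factor for blood vessels, from 67.6 ± 5.09 to 239 ± 68.3 CPM, 3.54-fold. By edgeR's quasi-likelihood test 3761 genes were higher and 4218 lower, 1046 and 543 of them by at least 2-fold. Groups did not overlap for 52.4% of genes, where chance gives 10%.

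Of 21 integrated stress response genes 17 rose and 3 fell, as also when adjusted over the list alone (camera adjusted p = 8.35e-12, and 0.0378 with an estimated correlation). The mitochondrial folate enzyme genes Aldh1l2 and Mthfd2 rose 12.6-fold and 3.44-fold. Of 18 hypoxia response genes 14 rose and 2 fell, and the same when adjusted over the list alone (camera adjusted p = 1.55e-06; adjusted p = 0.29 with an estimated correlation). Bnip3, which marks mitochondria for removal, rose from 17.9 ± 0.519 to 116 ± 40 CPM, and Pdk1, whose product inhibits pyruvate dehydrogenase, 2.74-fold. Of 14 glycolysis genes 9 rose and none fell, again 9 and 0 when adjusted over the list alone (camera adjusted p = 0.000387; adjusted p = 0.312 with an estimated correlation), with Pgk1 1.96-fold and Tpi1 1.62-fold higher. Of 21 respiratory chain genes 19 fell and none rose, as also when adjusted over the list alone (camera adjusted p = 9.85e-09; adjusted p = 0.174 with an estimated correlation), with Cox5a 1.72-fold and Cycs 1.52-fold lower. Of 21 collagen and matrix genes 13 rose and none fell, 14 and 0 when adjusted over the list alone (camera adjusted p = 1.79e-05; adjusted p = 0.29 with an estimated correlation), with Col3a1 9.89-fold and the fibronectin gene Fn1 1.88-fold higher.

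Of 23 cholesterol synthesis genes 22 fell and none rose, as also when adjusted over the list alone (camera adjusted p = 5.71e-16; adjusted p = 0.107 with an estimated correlation), with Msmo1 2.34-fold and Fdps 2.26-fold lower. Of 22 lysosome and autophagy genes 17 fell and 2 rose, 18 and 2 when adjusted over the list alone (camera adjusted p = 9.72e-08; adjusted p = 0.0688 with an estimated correlation), with Gpnmb 6.47-fold and Lamp1 1.85-fold lower. Beside these, the macrophage and microglia markers summed to 43.2 ± 3.94 CPM against 74.5 ± 3.91 CPM in PBS. Most of that fall was in the lysosomal gene Cd68 (15.8 against 42.7 CPM). The others moved either way, such as Csf1r (19.5 against 24.8 CPM) and Itgam (3.99 against 1.8 CPM). Of 24 DNA replication genes 18 fell and none rose, 19 and 0 when adjusted over the list alone (camera adjusted p = 4.95e-06; adjusted p = 0.312 with an estimated correlation), with Rrm2 1.53-fold lower. Of 20 G2 and mitosis genes 17 fell and none rose, 18 and 0 when adjusted over the list alone (camera adjusted p = 6.6e-06; adjusted p = 0.305 with an estimated correlation), with Plk1 1.46-fold and Kif20a 1.49-fold lower.

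Of 9 heat shock genes 8 fell and none rose, as also when adjusted over the list alone (camera adjusted p = 7.17e-05; adjusted p = 0.0845 with an estimated correlation), with Hsph1 1.94-fold lower. Of 17 endoplasmic reticulum chaperone genes 12 fell and 2 rose, 13 and 2 when adjusted over the list alone (camera adjusted p = 8.53e-05; adjusted p = 0.107 with an estimated correlation). Of 18 oxidative stress genes 10 fell and 2 rose, 11 and 2 when adjusted over the list alone (camera adjusted p = 0.00704; adjusted p = 0.12 with an estimated correlation). Of 13 STAT3 targets and regulators 9 rose and 1 fell, 10 and 1 when adjusted over the list alone (camera adjusted p = 6.58e-05; adjusted p = 0.12 with an estimated correlation), among them the cytokine receptor genes Osmr, 2.83-fold, and Il4ra, 2.24-fold. Of 12 Wnt target genes 8 rose and 1 fell, 9 and 1 when adjusted over the list alone (camera adjusted p = 0.00351; adjusted p = 0.387 with an estimated correlation).

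Among the largest rises were Tmprss6, a membrane protease gene of iron control, from 0.365 ± 0.28 to 22.7 ± 1.44 CPM, the iron-binding lipocalin gene Lcn2, 19.0-fold, and the alkaline phosphatase gene Alpl, 17.8-fold. Without PBS 3 the log2 difference of Tmprss6 rose from 5.96 to 6.75 and that of Lcn2 from 4.25 to 4.84. Sprr1b, which encodes a cornified envelope protein of epithelia, fell from 26.8 ± 2.43 to 1.99 ± 0.229 CPM. Cd44 was 1.30-fold lower (edgeR adjusted p = 3.27e-07) and Myc 1.21-fold higher (edgeR adjusted p = 0.00114). Nes was 1.67-fold higher (edgeR adjusted p = 0.0117), a call that ended without PBS 1 (0.0585), without PBS 2 (0.0827) and with limma on unfiltered log2(FPKM + 1) (0.0766). Abcb1a did not pass (45.6 ± 3.37 against 41.2 ± 1.88 CPM, edgeR adjusted p = 0.133), but did with upper-quartile factors (0.03) and without L-gel@GSNP 3 (0.0345). Abcg2 (edgeR adjusted p = 0.114) and Gfap (0.212) did not pass.

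Upper-quartile factors turned the balance of the calls, with 4560 genes higher and 3421 lower. Of 13 YAP targets, the remaining list, 6 rose and 2 fell, as also when adjusted over the list alone (camera adjusted p = 0.037; adjusted p = 0.494 with an estimated correlation). The call also ended in a fit of the 6 libraries alone (camera adjusted p = 0.0786), without PBS 1 (0.0645) and without L-gel@GSNP 3 (0.0727), over a range of 0.00756 to 0.494. The count at 2-fold was 1053 with a filter at 1 CPM and 289 on the log2(FPKM + 1) scale, in place of 1589.

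The comparison of D-gel@NP with PBS asks what the D hydrogel did with the other load. Genes of the integrated stress response rose, and cholesterol synthesis and mitosis genes fell by smaller amounts; only the stress response list passed with an estimated correlation. Asns rose 3.75-fold to 294 ± 19.6 CPM, Mthfd2 5.07-fold to 208 ± 17.6 CPM and Aldh1l2 14.4-fold to 73.8 ± 4.1 CPM. In edgeR's quasi-likelihood test 2479 genes were higher and 2848 lower, 493 and 184 of them by at least 2-fold. Groups did not overlap for 39.8% of genes, where chance gives 10%.

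Of 21 integrated stress response genes 19 rose and none fell, as also when adjusted over the list alone, with a mean log2 difference of 1.56 (camera adjusted p = 1.89e-30, and 0.000815 with an estimated correlation). Of 23 cholesterol synthesis genes 21 fell and none rose, 22 and 0 when adjusted over the list alone (camera adjusted p = 1.1e-11; adjusted p = 0.188 with an estimated correlation), with Hsd17b7 1.83-fold and Fdps 1.58-fold lower. Of 20 G2 and mitosis genes 18 fell and none rose, as also when adjusted over the list alone (camera adjusted p = 1.22e-09; adjusted p = 0.188 with an estimated correlation), with Kif23 1.52-fold and Aurka 1.38-fold lower. Of 24 DNA replication genes 10 fell and 2 rose, 10 and 3 when adjusted over the list alone (camera adjusted p = 0.0132; adjusted p = 0.7 with an estimated correlation). Of 21 respiratory chain genes 16 fell and none rose, 18 and 0 when adjusted over the list alone (camera adjusted p = 1.13e-07; adjusted p = 0.245 with an estimated correlation), with Cox5a 1.39-fold lower. Of 22 lysosome and autophagy genes 12 fell and 2 rose, 14 and 2 when adjusted over the list alone (camera adjusted p = 8.02e-05; adjusted p = 0.161 with an estimated correlation), with Gpnmb 1.91-fold lower. Macrophage and microglia markers summed to 40.1 ± 4.57 CPM here against 74.5 ± 3.91 CPM in PBS. Most of that fall was in the lysosomal gene Cd68 (16.5 against 42.7 CPM). The others moved either way, such as Csf1r (17 against 24.8 CPM) and Itgam (2.5 against 1.8 CPM).

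Of 18 oxidative stress genes 9 fell and 1 rose, as also when adjusted over the list alone (camera adjusted p = 0.00784; adjusted p = 0.161 with an estimated correlation), and the quinone reductase gene Nqo1 fell 1.97-fold. Of 9 heat shock genes 5 fell and none rose, 6 and 0 when adjusted over the list alone (camera adjusted p = 0.0115; adjusted p = 0.188 with an estimated correlation). Of 13 STAT3 targets and regulators 9 rose and none fell, again 9 and 0 when adjusted over the list alone (camera adjusted p = 3.82e-05; adjusted p = 0.161 with an estimated correlation), with Il4ra 1.62-fold and the kinase gene Pim1 1.49-fold higher. Of 21 collagen and matrix genes 9 rose and 1 fell, as also when adjusted over the list alone (camera adjusted p = 0.0115; adjusted p = 0.647 with an estimated correlation), with Fn1 1.73-fold higher. That call ended without PBS 1 (camera adjusted p = 0.0963, over a range of 3.69e-05 to 0.647). Tmprss6 rose 30.1-fold to 11.1 ± 1.29 CPM, the calcium pump gene Atp2a3 23-fold and the cysteine synthesis gene Cth 13.1-fold. Without PBS 3 the log2 difference of Tmprss6 rose from 4.91 to 5.71. Sprr1b fell 5.13-fold.

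Cd44 was 1.24-fold lower (edgeR adjusted p = 1.26e-05) and Myc 1.32-fold higher (edgeR adjusted p = 5.12e-05). Nes did not pass (edgeR adjusted p = 0.28) but did without PBS 3 (0.0147). Abcg2 (edgeR adjusted p = 0.558), Abcb1a (0.582) and Gfap (0.813) did not pass. Of 17 endoplasmic reticulum chaperone genes 8 fell and 2 rose, 9 and 3 when adjusted over the list alone (camera adjusted p = 0.0425; 0.383 with an estimated correlation). Of 14 glycolysis genes 6 fell and 1 rose, 6 and 2 over the list alone (0.04 and 0.677), and of 12 Wnt targets 5 rose and none fell, 6 and 0 over the list alone (0.035 and 0.647). These 3 lists lost their calls under several other alternatives too. Their camera adjusted p ran from 0.0129 to 0.383, from 0.0177 to 0.677 and from 0.00708 to 0.647 over all alternatives. Without PBS 1 they were 0.0979, 0.071 and 0.197, and without D-gel@NP 2 they were 0.0718, 0.109 and 0.0801. Upper-quartile factors gave 2974 genes higher and 2221 lower, and 102 genes in place of 677 passed the 2-fold limit on the log2(FPKM + 1) scale. D-gel@NP 1, the shallowest library, lay 34.8% further from the other libraries of its group than these lay from each other.

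**Figure D1:**
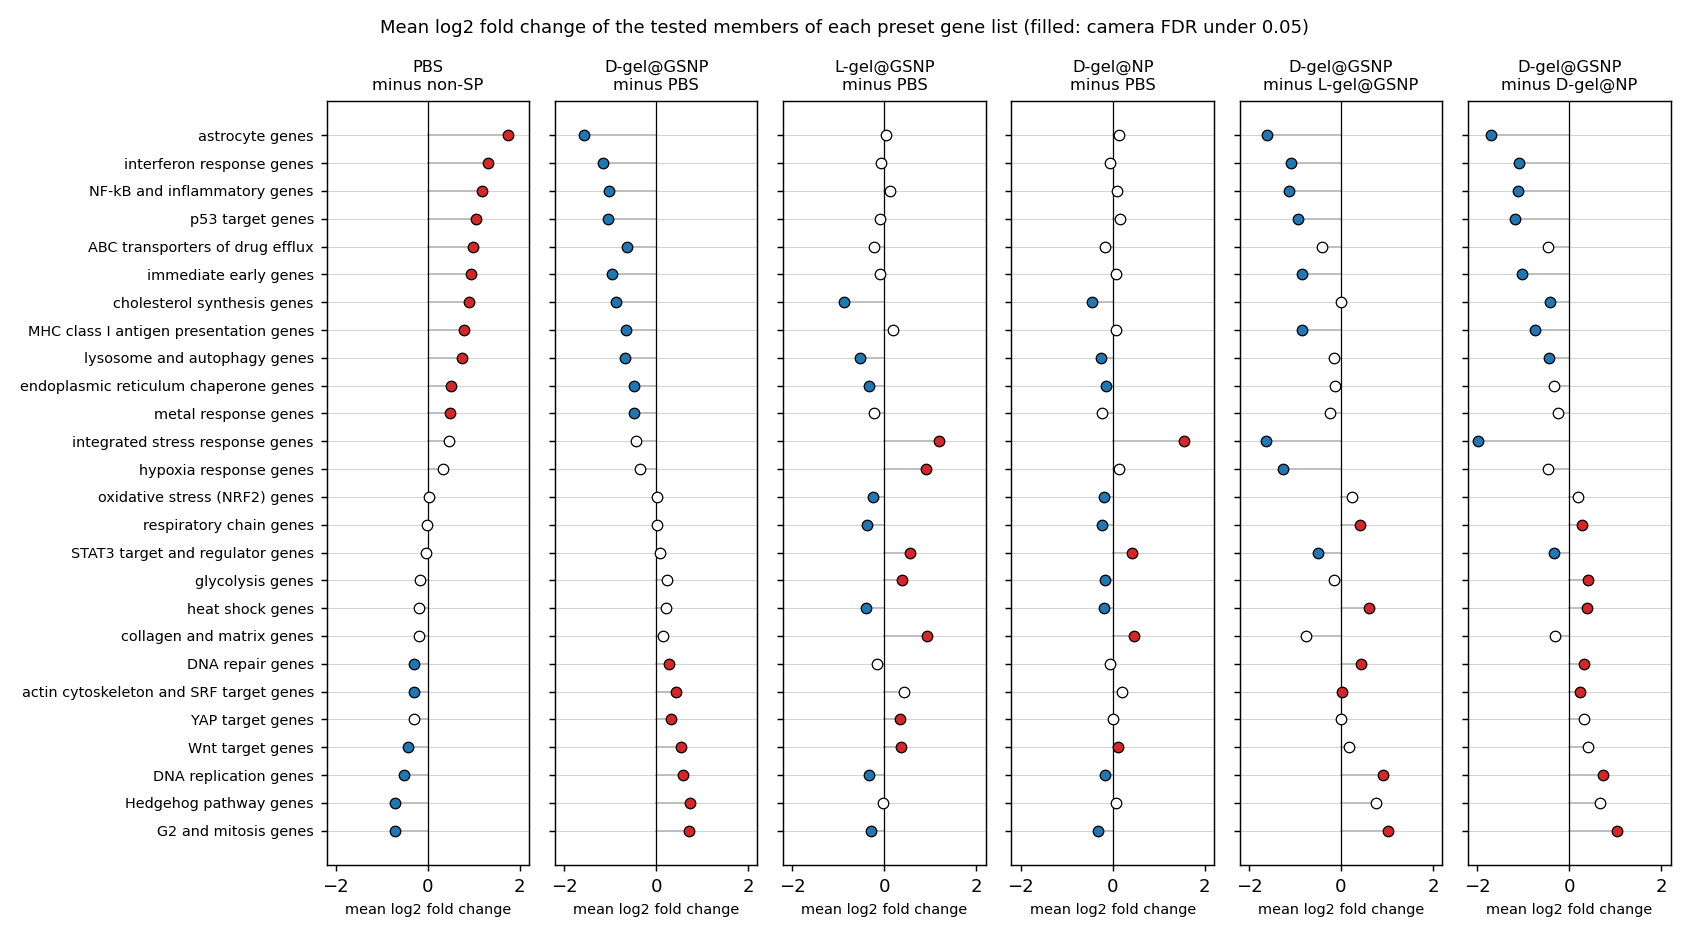
Mean log2 difference (x axis) of the tested members of preset gene lists (y axis) in the planned comparisons named above each panel, with a filled point where camera passed at an adjusted p under 0.05. In D-gel@GSNP minus PBS the G2 and mitosis list lies at 0.71 and the p53 list at -1.04, and in D-gel@NP minus PBS the integrated stress response list lies at 1.56.

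The direct comparison of D-gel@GSNP with L-gel@GSNP asks whether the 2 hydrogels, which carry the same load and differ in the prefix, differed. The limit given above for the D-gel@GSNP libraries holds here too. Most tested genes differed between the libraries of the 2 groups. Replication, mitosis, repair, respiratory chain and heat shock genes were higher in the D hydrogel, and integrated stress, hypoxia, p53, interferon and class I genes were lower. None of these lists passed with an estimated correlation (adjusted p 0.0935 to 0.346). Plk1 was 4.52-fold higher, at 155 ± 10.5 against 34.3 ± 3.61 CPM, and the stress-induced chromatin protein gene Nupr1 20.2-fold lower, at 4.22 ± 0.609 against 84.8 ± 4.49 CPM. By edgeR's quasi-likelihood test 5339 genes were higher and 5475 lower, 955 and 2465 of them by at least 2-fold. Groups did not overlap for 67.3% of genes, where chance gives 10%.

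Of 24 DNA replication genes 23 were higher and none lower, as also when adjusted over the list alone (camera adjusted p = 3.14e-12; adjusted p = 0.145 with an estimated correlation), with the chromatin assembly gene Chaf1a 2.58-fold and Mcm3 2.04-fold higher. Of 20 G2 and mitosis genes 19 were higher and none lower, again 19 and 0 when adjusted over the list alone (camera adjusted p = 2.55e-11; adjusted p = 0.145 with an estimated correlation). Of 23 DNA repair genes 20 were higher and 2 lower, as also when adjusted over the list alone (camera adjusted p = 5.5e-05; adjusted p = 0.163 with an estimated correlation), with Parp1 2.07-fold higher. Of 21 respiratory chain genes 18 were higher and none lower, as also when adjusted over the list alone (camera adjusted p = 1.91e-05; adjusted p = 0.337 with an estimated correlation), with Uqcrc1 2.33-fold higher. Of 9 heat shock genes 8 were higher and none lower, again 8 and 0 when adjusted over the list alone (camera adjusted p = 0.00066; adjusted p = 0.0952 with an estimated correlation), with Hspd1 2.06-fold higher.

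Of 21 integrated stress response genes 17 were lower and 3 higher, as also when adjusted over the list alone (camera adjusted p = 1.88e-07; adjusted p = 0.0935 with an estimated correlation), with Aldh1l2 19.9-fold lower. Of 18 hypoxia response genes 15 were lower and 2 higher, as also when adjusted over the list alone (camera adjusted p = 3.98e-05; adjusted p = 0.346 with an estimated correlation), with Bnip3 10.9-fold and Vegfa 7.74-fold lower. Of 22 p53 targets 18 were lower and 1 higher, again 18 and 1 when adjusted over the list alone (camera adjusted p = 6.52e-08; adjusted p = 0.0935 with an estimated correlation), with Trp53inp1 6.92-fold and Cdkn1a 2.22-fold lower. Of 26 interferon response genes 17 were lower and 1 higher, as also when adjusted over the list alone (camera adjusted p = 0.00135; adjusted p = 0.0935 with an estimated correlation), with Mx1 10.9-fold lower. Of 13 class I presentation genes 10 were lower and 1 higher, as also when adjusted over the list alone (camera adjusted p = 0.00343; adjusted p = 0.0935 with an estimated correlation), with Tapbp 1.81-fold lower. Of 9 astrocyte genes 7 were lower and none higher, as also when adjusted over the list alone (camera adjusted p = 0.00278; adjusted p = 0.103 with an estimated correlation). Macrophage and microglia markers summed to 12.8 ± 0.404 CPM in D-gel@GSNP and 43.2 ± 3.94 CPM in L-gel@GSNP, and the mitochondrial shares were 3.00% and 4.50%.

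The scaffold protein gene Akap12 was 9.42-fold higher at 103 ± 3.55 CPM, Gli1, a Hedgehog transcription factor gene, 9.30-fold higher at 19.4 ± 0.472 CPM, and the GABA-B receptor subunit gene Kctd12 7.30-fold higher. Tppp was 58.7-fold lower and Tmprss6 was at 0.125 ± 0.0714 against 22.7 ± 1.44 CPM. The metalloreductase gene Steap4 was at 0.521 ± 0.522 against 51.9 ± 3.11 CPM; its log2 difference of -6.53 became -7.86 without D-gel@GSNP 2. The immunoglobulin gene Ighm had no counts in D-gel@GSNP and 1201 in L-gel@GSNP, at least 310-fold lower against a floor of 3 counts over the group. Cd44 was 1.65-fold lower (edgeR adjusted p = 3.04e-12), Abcb1a 2.49-fold lower (edgeR adjusted p = 2.06e-12) and Nes 1.63-fold higher (edgeR adjusted p = 0.00672; 0.104 after thinning all libraries to the shallowest). Abcg2 (edgeR adjusted p = 0.872) and Myc (0.535) did not pass but were lower with upper-quartile factors (0.0185 and 0.00912), and Gfap did not pass (0.652).

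A further 4 lists passed camera. Of 15 immediate early genes 10 were lower and 2 higher, as also when adjusted over the list alone (camera adjusted p = 0.0118; adjusted p = 0.389 with an estimated correlation). Of 13 STAT3 targets and regulators 8 were lower and 1 higher, again 8 and 1 when adjusted over the list alone (camera adjusted p = 0.0164; adjusted p = 0.337 with an estimated correlation). Of 22 NF-kB and inflammatory genes 12 were lower and 4 higher, 12 and 5 when adjusted over the list alone (camera adjusted p = 0.0267; adjusted p = 0.346 with an estimated correlation); the call ended at 1 CPM (0.0672, over a range of 0.00509 to 0.346). The actin and SRF targets, 9 higher and 2 lower (10 and 3 when adjusted over the list alone), had a mean log2 difference of 0.02 and a median of 0.29, and passed camera as raised (adjusted p = 0.0353; adjusted p = 0.407 with an estimated correlation). With upper-quartile factors that mean turned to -0.12 and the call ended (camera adjusted p = 0.0689, over a range of 0.0043 to 0.407). Upper-quartile factors shifted the median of all genes to -0.184 and gave 4180 genes higher and 6778 lower, and 941 genes in place of 3420 passed the 2-fold limit on the log2(FPKM + 1) scale.

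The comparison of D-gel@GSNP with D-gel@NP asks what the load changed in the same kind of hydrogel, under the same limit for the D-gel@GSNP libraries. Mitosis and replication genes were higher with GSNP, and integrated stress response and p53 target genes lower; only the last 2 of these lists passed with an estimated correlation. Nupr1 was 27.2-fold lower at 4.22 ± 0.609 against 114 ± 6.1 CPM, Trp53inp1 8.90-fold lower at 62.6 ± 4.37 against 556 ± 40.2 CPM, and Plk1 4.31-fold higher. In edgeR's quasi-likelihood test 5031 genes were higher and 5183 lower, 787 and 2114 of them by at least 2-fold. Groups did not overlap for 62.5% of genes, where chance gives 10%.

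Of 21 integrated stress response genes 19 were lower and 1 higher, as also when adjusted over the list alone (camera adjusted p = 1.24e-12, and 0.0261 with an estimated correlation), with Aldh1l2 22.8-fold and Asns 3.16-fold lower. Of 22 p53 targets 19 were lower and none higher, again 19 and 0 when adjusted over the list alone (camera adjusted p = 1.24e-12, and 0.0261 with an estimated correlation), with Ccng1 2.65-fold lower. Of 20 G2 and mitosis genes 19 were higher and none lower, as also when adjusted over the list alone (camera adjusted p = 1.24e-12; adjusted p = 0.13 with an estimated correlation), with Aurka 2.96-fold higher. Of 24 DNA replication genes 23 were higher and none lower, as also when adjusted over the list alone (camera adjusted p = 3.44e-11; adjusted p = 0.194 with an estimated correlation), with Chaf1a 2.36-fold higher. Of 23 DNA repair genes 15 were higher and 2 lower, again 15 and 2 when adjusted over the list alone (camera adjusted p = 0.00129; adjusted p = 0.251 with an estimated correlation).

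Of 14 glycolysis genes 13 were higher and none lower, as also when adjusted over the list alone (camera adjusted p = 0.00219; adjusted p = 0.309 with an estimated correlation), with Eno1 1.31-fold higher. Of 21 respiratory chain genes 13 were higher and 1 lower, again 13 and 1 when adjusted over the list alone (camera adjusted p = 0.0015; adjusted p = 0.357 with an estimated correlation), with Uqcrc1 2.03-fold higher. Of 9 heat shock genes 7 were higher and 1 lower, as also when adjusted over the list alone (camera adjusted p = 0.0124; adjusted p = 0.21 with an estimated correlation), with Hspd1 1.69-fold higher. Of 14 actin and SRF targets 10 were higher and 1 lower, again 10 and 1 when adjusted over the list alone (camera adjusted p = 0.00203; adjusted p = 0.251 with an estimated correlation). Of 26 interferon response genes 18 were lower and 1 higher, 18 and 2 when adjusted over the list alone (camera adjusted p = 0.000532; adjusted p = 0.0684 with an estimated correlation), with Mx1 18.2-fold lower. Of 22 lysosome and autophagy genes 15 were lower and 2 higher, again 15 and 2 when adjusted over the list alone (camera adjusted p = 0.000524; adjusted p = 0.136 with an estimated correlation), with Ctsd 3.26-fold lower. Macrophage and microglia markers summed to 12.8 ± 0.404 CPM in D-gel@GSNP and 40.1 ± 4.57 CPM in D-gel@NP.

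Of 13 class I presentation genes 10 were lower and 1 higher, 11 and 1 when adjusted over the list alone (camera adjusted p = 0.0052; adjusted p = 0.102 with an estimated correlation). Of 22 NF-kB and inflammatory genes 13 were lower and 3 higher, 13 and 4 when adjusted over the list alone (camera adjusted p = 0.00709; adjusted p = 0.251 with an estimated correlation), with Cxcl5 5.42-fold lower. Of 23 cholesterol synthesis genes 14 were lower and 3 higher, again 14 and 3 when adjusted over the list alone (camera adjusted p = 0.00139; adjusted p = 0.372 with an estimated correlation), with Msmo1 2.73-fold lower. Of 9 astrocyte genes 7 were lower and none higher, as also when adjusted over the list alone (camera adjusted p = 0.000956; adjusted p = 0.0902 with an estimated correlation). Of 15 immediate early genes 10 were lower and 2 higher, 12 and 2 when adjusted over the list alone (camera adjusted p = 0.00208; adjusted p = 0.274 with an estimated correlation).

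Akap12 was 6.02-fold and Kctd12 4.87-fold higher with GSNP, and Tppp 67.0-fold and Aqp1 32.3-fold lower. Cd44 was 1.73-fold lower (edgeR adjusted p = 1.02e-12), Abcb1a 2.36-fold lower (edgeR adjusted p = 9.55e-12) and Nes 2.11-fold higher (edgeR adjusted p = 0.000329). Myc was 1.13-fold lower (edgeR adjusted p = 0.022), a call that ended without D-gel@GSNP 1 (0.0678), D-gel@GSNP 3 (0.148) or D-gel@NP 2 (0.121). Abcg2 did not pass (edgeR adjusted p = 0.29) but was lower with upper-quartile factors (0.00583) and with limma on log2(FPKM + 1) (0.0348), and Gfap did not pass (0.636). Of 13 STAT3 targets and regulators, the remaining list, 6 were lower and 1 higher, as also when adjusted over the list alone (camera adjusted p = 0.042; adjusted p = 0.309 with an estimated correlation). The call also ended at 1 CPM (camera adjusted p = 0.0521), without D-gel@GSNP 3 (0.0501) and without D-gel@NP 1 (0.0696), over a range of 0.00678 to 0.309. Upper-quartile factors shifted the median of all genes to -0.157 and gave 3961 genes higher and 6303 lower, and 727 genes in place of 2901 passed the 2-fold limit on the log2(FPKM + 1) scale.

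**Figure D2:**
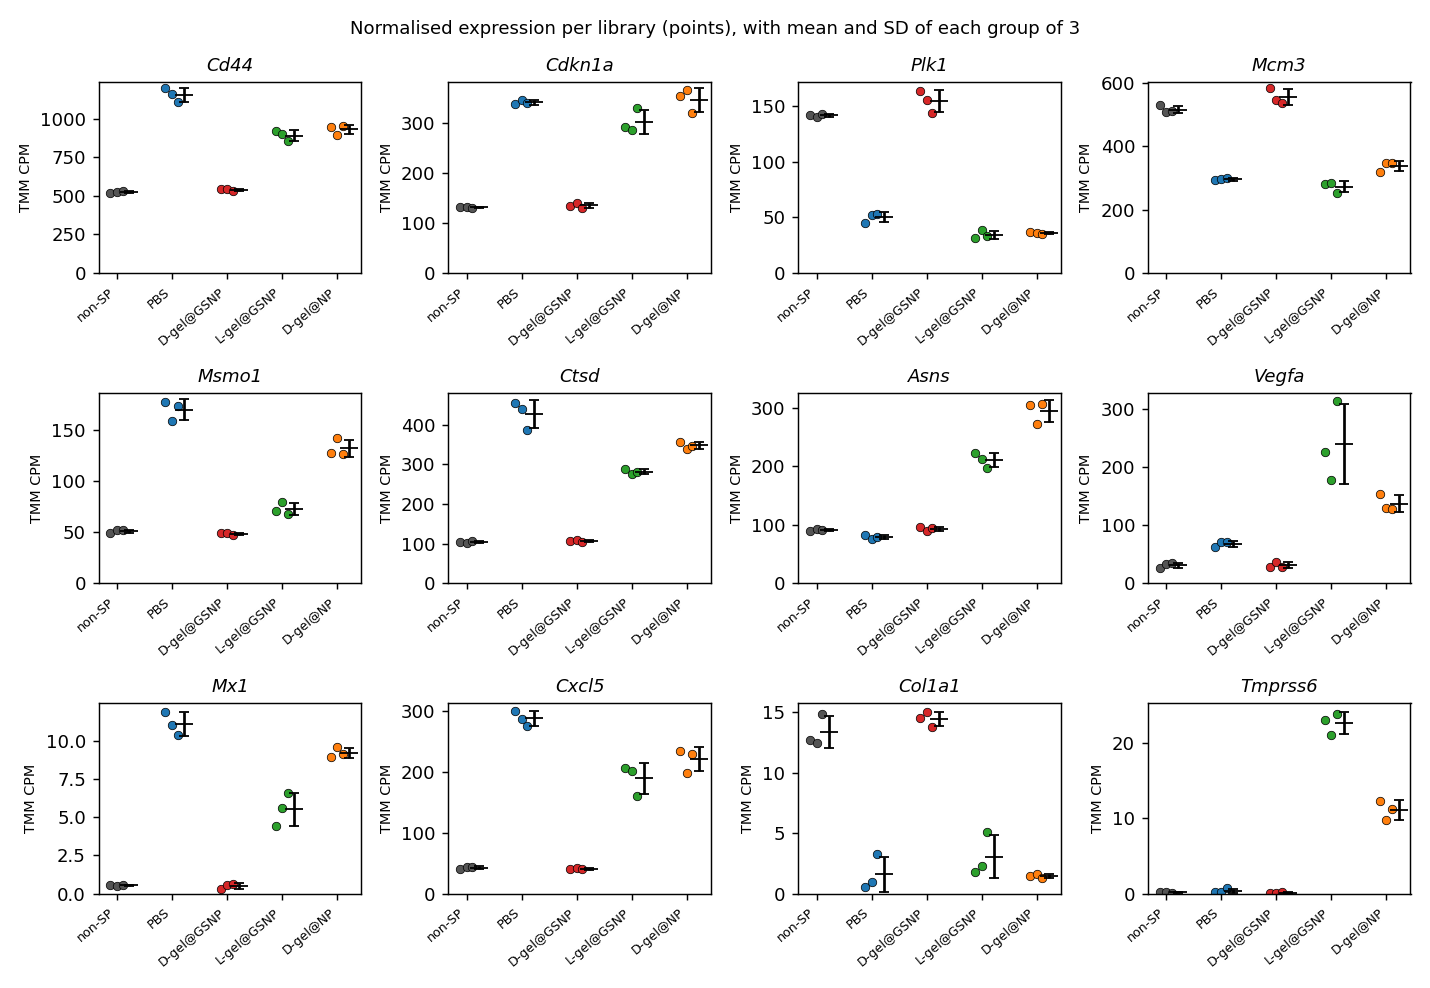
TMM-normalised CPM of 12 named genes (y axes, starting at 0) in each library by group (x axes); points are libraries, and the bar beside them gives mean and SD (n = 3). For Cdkn1a the D-gel@GSNP mean of 136 CPM lies beside the non-SP mean of 132 CPM, while the PBS mean is 341 CPM.

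The comparisons with non-SP ask how close each treated group came to the untreated cells outside the side population. D-gel@GSNP was nearly level with non-SP: Cd44 was at 539 ± 6.97 against 523 ± 5.85 CPM (edgeR adjusted p = 0.806), Abcb1a at 18.3 ± 1.51 against 18 ± 0.834 CPM (0.971) and Abcg2 at 50 ± 1.78 against 48 ± 0.866 CPM (0.811). Nes was at 3.38 ± 0.221 against 3.7 ± 0.152 CPM (edgeR adjusted p = 0.895), Myc at 192 ± 15.3 against 195 ± 2.08 CPM (0.937) and Gfap at 0.181 ± 0.123 against 0.105 ± 0.0687 CPM (0.817). By edgeR's quasi-likelihood test 18 genes were higher and 55 lower, 7 and 15 of them by at least 2-fold; 1581 had an unadjusted p under 0.05, and DESeq2 called 196. Of 10204 genes with a mean of at least 5 CPM in the higher group, the 95% interval of the difference lay within 2-fold for 10173 (99.7%), against 86.2% for D-gel@GSNP minus PBS. Over all 17497 tested genes, many of them with few counts, it did so for 73.68% against 60.3%. Groups did not overlap for 20.4% of genes, where chance gives 10%.

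No member of any of the 3 lists that camera called between D-gel@GSNP and non-SP passed the gene test, and their mean log2 differences were small. These were the actin and SRF targets at 0.13 (camera adjusted p = 0.0127), the lysosome and autophagy genes at 0.07 (0.0127) and the DNA replication genes at 0.06 (0.0216). Adjusted over the list alone, 1 actin gene (Vcl, vinculin) and 1 lysosome and autophagy gene (Gabarapl1) rose, both named after their values were seen. With an estimated correlation the camera adjusted p was 0.916, 0.911 and 0.932, and without D-gel@GSNP 1 it was 0.149, 0.353 and 0.394. The count of 73 genes was not stable. It was 10, 9 and 8 without non-SP 1, 2 or 3, and 6, 9 and 140 without D-gel@GSNP 1, 2 or 3. It was 239 without a filter, 34 with the replicate number in the fit, 282 in a fit of the 6 libraries alone and 28 on the log2(FPKM + 1) scale.

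L-gel@GSNP and D-gel@NP remained far from non-SP. In edgeR's quasi-likelihood test 5361 genes were higher and 5107 lower in L-gel@GSNP than in non-SP, 2310 and 840 of them by at least 2-fold, and groups did not overlap for 66.6% of genes. For D-gel@NP 5098 were higher and 4725 lower, 1968 and 669 by at least 2-fold, and groups did not overlap for 62.1% (chance gives 10%). In L-gel@GSNP 17 of 21 integrated stress response genes were higher and 3 lower, as also when adjusted over the list alone (camera adjusted p = 1.77e-08; adjusted p = 0.0691 with an estimated correlation), and in D-gel@NP 19 and 1 (camera adjusted p = 5.41e-14, and 0.0199 with an estimated correlation). All but 1 of 20 G2 and mitosis genes were lower in either group, as also when adjusted over the list alone (camera adjusted p = 1.62e-12 and 5.41e-14; adjusted p = 0.117 and 0.0857 with an estimated correlation). Of 22 p53 targets 18 were higher and 1 lower in L-gel@GSNP (camera adjusted p = 1.31e-08; adjusted p = 0.0691 with an estimated correlation) and 21 were higher and none lower in D-gel@NP (camera adjusted p = 1.24e-13, and 0.0199 with an estimated correlation), the same counts as when adjusted over the list alone. Upper-quartile factors shifted the median of all genes to 0.16 and 0.134 and gave 6472 and 4106 genes for L-gel@GSNP and 6016 and 3859 for D-gel@NP. On the log2(FPKM + 1) scale 859 and 662 genes passed the 2-fold limit.

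The differences from PBS were shared between L-gel@GSNP and D-gel@NP more than with D-gel@GSNP. L-gel@GSNP and D-gel@NP had 4402 genes called in the same direction and 41 in opposite directions, where independent calls would give 1219. D-gel@GSNP and L-gel@GSNP had 2823 in the same and 2531 in opposite directions (independent calls, 2194), and D-gel@GSNP and D-gel@NP 1969 and 1761 (1465). The numbers for independent calls are for the same direction only. The 3 PBS libraries could not be divided between the comparisons, so the shared control can add to the counts in the same direction. It does not add to the 2531 and 1761 genes in opposite directions. For the D-gel@GSNP pairs, a count above that of independent calls therefore does not by itself show a shared direction. Over all tested genes the covariance of the log2 differences was 0.364 for L-gel@GSNP and D-gel@NP, against 0.056 in 20 simulations without group differences that shared the PBS libraries. It was 0.101 (0.056 simulated) for D-gel@GSNP and L-gel@GSNP and 0.054 (0.057 simulated) for D-gel@GSNP and D-gel@NP, so no sharing beyond the control is shown for the last pair. With changes of at least 2-fold only, the shared counts were 533, 358 and 139.

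The adjusted p-values above measure the spread between these libraries only; the labels do not say whether replicates were separate sorts, cultures or gels. Each fit used 3 libraries per group, and the values of genes at a few counts carry counting error as well.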

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

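None of the tests in this part was chosen after its result was seen, but the 2 lists were picked by their results. They are given here because their difference from PBS went in opposite directions in the D and the L hydrogel groups with the same load. The mean log2 difference of the DNA replication genes was 0.58 in D-gel@GSNP minus PBS and -0.33 in L-gel@GSNP minus PBS, and the direct difference of the 2 groups was 0.91 (camera adjusted p = 3.14e-12; adjusted p = 0.145 with an estimated correlation). The G2 and mitosis genes were at 0.71 and -0.3 against PBS, with a direct difference of 1.02 (camera adjusted p = 2.55e-11; adjusted p = 0.145 with an estimated correlation). The direct differences follow from how the lists were picked, so they add no separate support. The weighing of the D-gel@GSNP libraries among the other observations bears on both lists.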

How the results depend on the processing

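Thinning and leaving out mitochondrial genes or D-gel@NP 1 in every fit were chosen only after the data were seen; the other alternatives were planned. Named genes gave 4136 values for 224 results, of which 4095 kept direction and side of the threshold, 10 lost the call, 15 gained it and 16 turned direction; 206 results kept both under every alternative. Lists with the preset correlation gave 1678 values for 115 results, of which 1623 kept camera's direction and call and 55 lost the call; 94 results kept both throughout. With an estimated correlation 19 of 115 list calls were kept and 96 lost; an estimated correlation takes in that members vary together. The lists called then were 7 for PBS minus non-SP, 3 for D-gel@GSNP minus PBS, 1 for L-gel@GSNP minus PBS, 1 for D-gel@NP minus PBS, 0 for D-gel@GSNP minus L-gel@GSNP and 2 for D-gel@GSNP minus D-gel@NP.

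The count of genes for D-gel@GSNP minus non-SP (73, of which 22 at least 2-fold) moved by over 1.5 times under 14 of 19 alternatives. It was 79 with RLE and 99 with upper-quartile factors, 80 with at least 1 CPM in 3 libraries, 70 without mitochondrial genes and 71 without D-gel@NP 1 in the fit. Without a filter it was 239 (58 at least 2-fold), with a replicate block 34 (11), with DESeq2 196, with only the 6 libraries 282 (36), and after thinning 32 (3). With limma it was 28 (3) on log2(FPKM + 1), 36 (6) on log2(FPKM + 0.1) and 11 (1) on log2(FPKM + 1) without a filter. Without a single library it ran from 6 to 140 (3 to 21). The highest of these, 140, came without D-gel@GSNP 3; the cause of these shifts was not tested. The replicate block was checked because groups share replicate numbers: 30 pairs of libraries with the same number correlated at -0.036 to 0.045 after removing group means, and 3 of 15 libraries correlated best with their own number.

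For the 8 other planned comparisons the count of called genes lay between 4181 (D-gel@NP minus PBS without PBS 2) and 11001 (D-gel@GSNP minus L-gel@GSNP without D-gel@NP 1 in the fit). The count at 2-fold for L-gel@GSNP minus PBS was 1053 with at least 1 CPM in 3 libraries. Counts at 2-fold were lower on FPKM scales, where the added value shrinks changes of weakly expressed genes by construction; other causes were not tested. In the order PBS minus non-SP, D-gel@GSNP, L-gel@GSNP and D-gel@NP minus PBS, D-gel@GSNP minus L-gel@GSNP, D-gel@GSNP minus D-gel@NP, L-gel@GSNP and D-gel@NP minus non-SP, they were 511, 530, 289, 102, 941, 727, 859 and 662 on log2(FPKM + 1). They were 999, 1068, 627, 238, 1707, 1416, 1544 and 1289 on log2(FPKM + 0.1), and 506, 529, 282, 94, 935, 720, 855 and 654 without a filter. Overlaps at 2-fold were smaller by construction: 358 for D-gel@GSNP and L-gel@GSNP, 139 for D-gel@GSNP and D-gel@NP, 533 for L-gel@GSNP and D-gel@NP, and for PBS minus non-SP in the opposite direction 1676 with D-gel@GSNP, 368 with L-gel@GSNP and 145 with D-gel@NP.

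The 16 values of named genes that turned direction all belonged to panel genes that were not called. Besides these, 6 list means of 4 results changed sign: actin and SRF targets in D-gel@GSNP minus L-gel@GSNP (-0.12 with upper-quartile factors, -0.06 without D-gel@GSNP 2, -0.05 without L-gel@GSNP 2) and, without a filter, the Hedgehog list (-0.24) and Wnt targets (-0.09) in D-gel@GSNP minus PBS and Wnt targets (-0.09) in D-gel@NP minus PBS. Only the first of these 6 ended the camera call, whose direction rests on all genes. Abcb1a in D-gel@GSNP minus non-SP had log2 differences of -0.008 with upper-quartile factors, -0.01 with the 6 libraries, -0.016 on log2(FPKM + 1) with and without a filter, and -0.02 on log2(FPKM + 0.1). Without a single library it ran from -0.029 to 0.084. Over the same leaving out, Myc ran from -0.089 to 0.027 in D-gel@GSNP minus non-SP and from -0.108 to 0.009 in D-gel@GSNP minus L-gel@GSNP. Abcg2 ran from -0.075 to 0.003 in D-gel@NP minus PBS, where thinning also gave 0.003, and from -0.037 to 0.021 in D-gel@GSNP minus L-gel@GSNP. Gfap ran from -0.529 to 0.059 in D-gel@NP minus PBS, from -0.214 to 0.825 in D-gel@GSNP minus L-gel@GSNP and from -0.975 to 0.062 in D-gel@GSNP minus D-gel@NP. The cause was not tested.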

Other observations

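The comparison of L-gel@GSNP with D-gel@NP and the tests of keratins and of pseudogenes were chosen only after the result was seen, as was the use of the pooled part kept, and the tests of the median part kept and of depth were chosen after the pattern was seen but before their own values were. L-gel@GSNP and D-gel@NP differ in both the hydrogel and the load. In L-gel@GSNP minus D-gel@NP, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1457 genes higher and 1948 lower, of which 211 and 107 at least 2-fold. The balance turned with upper-quartile factors (1720 higher, 1645 lower), and the 318 genes at 2-fold became 28 on log2(FPKM + 1), 103 on log2(FPKM + 0.1) and 25 on log2(FPKM + 1) without a filter. Of 14 glycolysis genes 12 rose and none fell, 12 and 0 when adjusted over the list alone (mean log2 difference 0.56, camera adjusted p = 2.54e-15; 0.0436 with an estimated correlation). Of 18 hypoxia response genes 15 rose and none fell, 15 and 1 (Bhlhe40, named after its values were seen) when adjusted over the list alone (mean 0.78, camera adjusted p = 1.93e-13; 0.08 with an estimated correlation). Vegfa, picked after its values were seen, was at 226, 178 and 313 CPM in the L-gel@GSNP libraries and at 153, 129 and 128 CPM in the D-gel@NP libraries. Of 23 cholesterol synthesis genes 20 fell and none rose, 20 and 0 when adjusted over the list alone (mean -0.42, camera adjusted p = 2.54e-15; 0.08 with an estimated correlation), and of 21 integrated stress response genes 14 fell and none rose, 16 and 0 when adjusted over the list alone (mean -0.38, camera adjusted p = 5.04e-11; 0.0436 with an estimated correlation).

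The summed level of pericyte and fibroblast markers was 708 CPM in non-SP, 1350 in PBS, 680 in D-gel@GSNP, 1420 in L-gel@GSNP and 1500 in D-gel@NP, most of it from Dcn (659, 1290, 630, 1400 and 1470 CPM). Endothelial markers summed to 7.09, 20, 5.77, 9.33 and 14.3 CPM in the same order of groups. Most of the difference came from Vwf (1.29, 15.9, 1.19, 6 and 10.1 CPM), while Flt1 was highest in non-SP (4.85, 2.59, 3.47, 2.26 and 3.12 CPM). These are levels only, and no cell type was tested for.

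The D-gel@GSNP libraries lay close to the non-SP libraries, with 73 genes called. A remainder of PBS-like cells would keep part of the PBS profile, and over 32 to 37 genes at least 8-fold higher in PBS the median part kept was 0.37%, 0.32% and -0.4% in the D-gel@GSNP libraries, against -0.1% to 0.33% in non-SP libraries left out. A value under the highest non-SP library was set beforehand to count against a remainder, and 0.32% and -0.4% met this. The pooled part, looked at only after these values were seen, was 0.33%, 0.59% and 1.75% in the same order. The highest non-SP value was 0.61%. This excess rests on 1 library and a measure chosen late, so it does not overturn the planned outcome. The 2 measures differ in that library, so a small remainder is not excluded. The median part was 65.6% to 78.8% in L-gel@GSNP and 76.0% to 86.4% in D-gel@NP. The pooled part was 94.4% to 99.4% in L-gel@GSNP and 92.8% to 98.8% in D-gel@NP. The genes were picked by their level in the same PBS libraries, which can lower the part kept in the other groups. A wrong label or shared material is a technical explanation, and a treatment that brings the cells to the non-SP state is a biological explanation. For a wrong label or shared material, every D-gel@GSNP median part was set to lie within the non-SP range, and 0.37% and -0.4% did not. To count against it, every one had to lie above the highest non-SP value, and 0.32% and -0.4% did not. The outcome lay between these, so the 2 explanations cannot be told apart from the counts. The groups did not overlap for 20.4% of genes, where chance gives 10%, so they differed slightly, and the cause of that was not tested.

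Epithelial keratins were abundant in every group. Of 7 epithelial markers, 4 had a highest group mean at least 1.5 times the lowest: Krt19 (95.3 to 198 CPM), Epcam (10.8 to 21.2), Cldn4 (21.2 to 42.2) and Cdh1 (0.393 to 0.814). Krt18 (995 to 1100 CPM), Krt8 (717 to 974) and Cldn3 (93.9 to 129) moved less, and the markers were not highest in the same group. Krt19 was highest in PBS and Cldn3 in non-SP, which argues against a differing epithelial share as the only cause for these markers. The outcome lay between those set for and against such a share, so a differing share beside other changes stays open. The epithelial marker median exceeded the glial and neural median in 15 of 15 libraries (85.0 to 120 CPM against 0.0254 to 0.225 CPM). Expression of keratins by the main cells of the line, a biological explanation, and a share of epithelial cells, constant or not, a technical one, cannot be told apart, because bulk counts do not show which cells the reads came from.

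D-gel@NP 1 lay 34.8% further from the other libraries of its group than these lay from each other. After thinning the excess was 13.4% (12.5% to 14.6% over 10 draws), against at most 4.6% for another library. This is of the size set beforehand to count against its lower depth as the cause. But thinning drew each count singly and left D-gel@NP 1, the shallowest library, unchanged. If mates of a pair were counted separately, that would lower the spread of the deeper libraries only, so depth as the whole cause stays open. Pseudogenes were 4.85 times more frequent among the genes that differed in this library (34 of 121) than among the genes compared (738 of 12732, Fisher's exact test p = 4.48e-15). Reads shared with parent genes, a technical explanation, could give such an excess. It was not computed for any other library, so it does not show what sets this library apart. Fisher's test does not allow for expression level, and a biological difference of this culture was not tested.

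The 6 libraries of each comparison were also split in all 10 ways, and 10 splits are too few for a share under 0.05. Genes called in the real split and the highest number in any other were 9347 and 0 for PBS minus non-SP, 9381 and 1 for D-gel@GSNP minus PBS, 7319 and 0 for L-gel@GSNP minus PBS, and 4453 and 0 for D-gel@NP minus PBS. They were 10624 and 0 for D-gel@GSNP minus L-gel@GSNP, 9807 and 0 for D-gel@GSNP minus D-gel@NP, and 282 and 2 for D-gel@GSNP minus non-SP. They were 10403 and 0 for L-gel@GSNP minus non-SP, 9585 and 0 for D-gel@NP minus non-SP, and 2540 and 1 for L-gel@GSNP minus D-gel@NP.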
